A study of Rattus norvegicus with 72 samples.

How the data were processed

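Total RNA of primary rat hepatocytes was labelled with biotin and hybridised to Affymetrix rat arrays, 1 sample per array, 72 arrays in all. Per the submitters' processing notes the values were made with MAS5, which gives 1 background-corrected intensity per probe set from its perfect-match and mismatch probes; the version and settings are not given in the sources used here. The deposited table holds these intensity values on a linear scale for 31099 probe sets, and every array's mean without the top and bottom 2% was close to 100, as the values themselves show. No column of values was left unused (0). The number of arrays, 3 per group, limits the precision of each value.

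Groups and replicate numbers were taken from the titles, which also give a D number whose meaning the labels do not state. The protocol speaks of independent biological experiments for each compound. The p-values rest on the spread between arrays within groups, pooled over all groups, and do not use the pairing of arrays by D number. The 24 groups were 8 compounds and 4 control groups at 2 exposure times. Values were raised to a floor of 3.117, the 20th percentile of the table, and put on the log2 scale. A fold change of a gene near the floor is therefore understated, and where all 3 arrays of the dimmer group were at the floor it is given as a lower bound. The 57 control probe sets were left out, and a probe set was kept where the mean of at least 1 group reached the median of all values, 19.74, which kept 18048 (58.1%). Other normalization was not applied.

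The differences were tested with limma 3.58.1 in R 4.3.3, by lmFit on the means of the 24 groups (48 residual degrees of freedom) and eBayes with an intensity trend, with Benjamini-Hochberg adjustment within each comparison and an adjusted p under 0.05 as the threshold. All groups share 1 estimate of the spread per probe set, so that noisy arrays in one set would widen the spread used for every comparison. For the noisy set itself the shared spread can be too small. Macrod1 after 72 h of aflatoxin B1 has an SE of 0.50, beside an SD of 2.42 over the 3 treated arrays. Each compound was set against its own control at the same time, which makes 16 comparisons. The same fit gave the difference of effects between 72 h and 24 h, the mean effect of the genotoxic against the non-genotoxic carcinogens and of the carcinogens against the non-carcinogens, the change from 24 h to 72 h in the controls, and the difference between the controls of NNK and of the 2-nitrofluorene set. Comparisons that share controls share their chance values, and overlaps of calls are given only between comparisons with no arrays in common. The 24 h and 72 h arrays of a compound share D numbers, and the overlaps by chance take the lists as independent.

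Gene names came from the platform annotation that goes with the table, in which 20826 probe sets have 1 symbol, 436 several and 9780 none, beside the 57 control probe sets. Of the kept probe sets 14072 have 1 symbol, and each of the 10178 genes was represented by its probe set of highest mean. For the 16 comparisons the genes to be named were fixed before the data were examined: the 10 largest rises and 10 largest falls, up to 4 called members of each gene list with the largest changes, and 24 fixed genes whether called or not. The rises and falls were taken from called genes with the same sign in all 3 pairs of equal number and a brighter mean at or above the table's median. A further condition, no group with all its arrays at the floor, was added after that and left out 17 gene results in 8 contrasts, such as Lrmda after 72 h of aflatoxin B1 (−4.14 ± 0.65). None of these conditions was asked of the list members, such as Acot1 after Wy-14643. The other contrasts used the first part alone. The text names fewer, in order of size, and was narrowed after the data were seen to genes that mostly kept their call with each array left out, with the exceptions given beside their values. S100a14 and Aebp2 were added after their values were seen.

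The 18 gene lists were also fixed before the data were examined: p53 and DNA damage, PPARα, AhR, CAR and PXR, NRF2, ER stress and ATF4 targets, cholesterol synthesis, fatty acid synthesis, bile acid synthesis and transport, cell cycle, hepatocyte function, acute phase, cytoskeleton, foetal liver, and markers of stellate cells, macrophages, endothelial cells and bile duct cells. Of their measured members 1 of the p53 list, 1 of the PPARα list, 1 of the AhR list, 4 of the NRF2 list, 1 of the ER stress list, 4 of the foetal list and 2 of the bile duct list stand in another list too. Lists were tested with camera at an estimated correlation between genes, adjusted over 288 tests, with a preset correlation of 0.01 as an alternative. Counts of members that passed are given over all probe sets and adjusted over the list alone. The mean change of the p53 list per compound was compared between the 3 genotoxic compounds and the other 5 with an exact permutation test.

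The replicate numbers were checked for pairing by the correlation of deviations from the group means between arrays of equal number. Every pair was above 0.1 in 14 of the 16 comparisons (0.268 to 0.829), and there the counts with the D number as a block (42 residual degrees of freedom) stand beside the results, for example 600 and 1296 for NNK at 72 h. The block gives each D number a single effect shared by 24 h and 72 h. Pairing was checked within each time, so the block is not a paired test at each time. RNA quality was read from the 3′ over 5′ signal of the beta-actin control probe sets, with 1.5 on the log2 scale as the threshold. The alternatives fixed beforehand were the replicate block, no filter, quantile normalization, no floor, eBayes without the trend, the preset correlation, the median of the p53 list, and leaving out each array or replicate number in turn. Added after seeing the data were fits without the 10 arrays over the actin threshold, which leave 1 aflatoxin B1 array at each time, assumed to vary like the other groups, with the actin ratio as a covariate, and without the 8 arrays of D number 3.

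The scripts were tested on simulated data for NNK at 72 h over 18048 probe sets, with 50 changed for each fold. At log2 changes of −2, −1, 1 and 2 they recovered 94%, 72%, 68% and 94% of the changed probe sets, with mean estimates of −2.04, −1.01, 0.982 and 2.03. Of the unchanged probe sets 11 were called, and the changed ones were drawn from probe sets above the median signal. With the replicate block 162 changed probe sets were called, no more than without it. In the real data the block raised the count for NNK at 72 h. The simulation thus did not show the gain from pairing of the real arrays, and its shares need not hold for them. Figures were drawn with matplotlib 3.10.9.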

Results

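The data were expression profiles of primary rat hepatocytes, liver cells taken freshly from the animal and kept as a conventional monolayer, after exposure to 8 compounds. The series set out to compare the profiles of carcinogens in this culture with those in rat liver, and the liver profiles are not analysed here. Its design text names 3 compounds as genotoxic carcinogens: aflatoxin B1, a mould toxin (19 nM), the tobacco nitrosamine 4-(methylnitrosamino)-1-(3-pyridyl)-1-butanone, below NNK (625 µM), and 2-nitrofluorene (78 µM). It names 3 as non-genotoxic carcinogens: Wy-14643, an agonist of the lipid receptor PPARα (250 µM), piperonyl butoxide, an insecticide synergist (13.4 µM), and the antihistamine methapyrilene (8.5 µM). The 2 non-carcinogens were nifedipine, a calcium channel blocker (156 µM), and clonidine, an α2-adrenergic agonist (277 µM). RNA was taken after 24 h and 72 h of exposure, with 3 arrays per compound and time from independent experiments. Wy-14643, clonidine and aflatoxin B1 shared 1 control group per time, as did 2-nitrofluorene, piperonyl butoxide and nifedipine, while NNK and methapyrilene had controls of their own. That made 24 groups and 72 arrays.

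The array signals were scaled alike, with array medians from 15.76 to 23.8 and 17.4% to 23.9% of values at or under the floor. No pair of arrays was a copy of another, as the highest correlation between any 2 was 0.985. The log2 ratio of 3′ over 5′ signal of beta-actin, which rises as RNA degrades, lay between 0.36 and 1.11 on 62 arrays and between 1.84 and 2.71 on the other 10. These 10 were the replicate 3 arrays of the Wy-14643, clonidine and aflatoxin B1 set with their controls (8 arrays, D number 3 in their titles), aflatoxin B1 replicate 1 at 24 h and aflatoxin B1 replicate 2 at 72 h. A score of culture time was taken from 5333 probe sets that differed between 24 h and 72 h in the controls of the other sets (0 for their 24 h mean, 1 for their 72 h mean). From 24 h to 72 h it rose by 0.694 ± 0.255 (SD) over 21 pairs of arrays of the same treatment and number, leaving out the 9 control pairs that set the score. Among them were 6 pairs of D numbers 1 and 2, from the same set as D number 3, with 0.553 ± 0.191. In 2 more pairs, which hold a high actin array, it rose by 0.651 ± 0.0826. In the 4 pairs of D number 3 it ran the other way, by −0.510 ± 0.117 (SD). For these 8 arrays the exposure times below are therefore those of the labels.

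**Figure D1:**
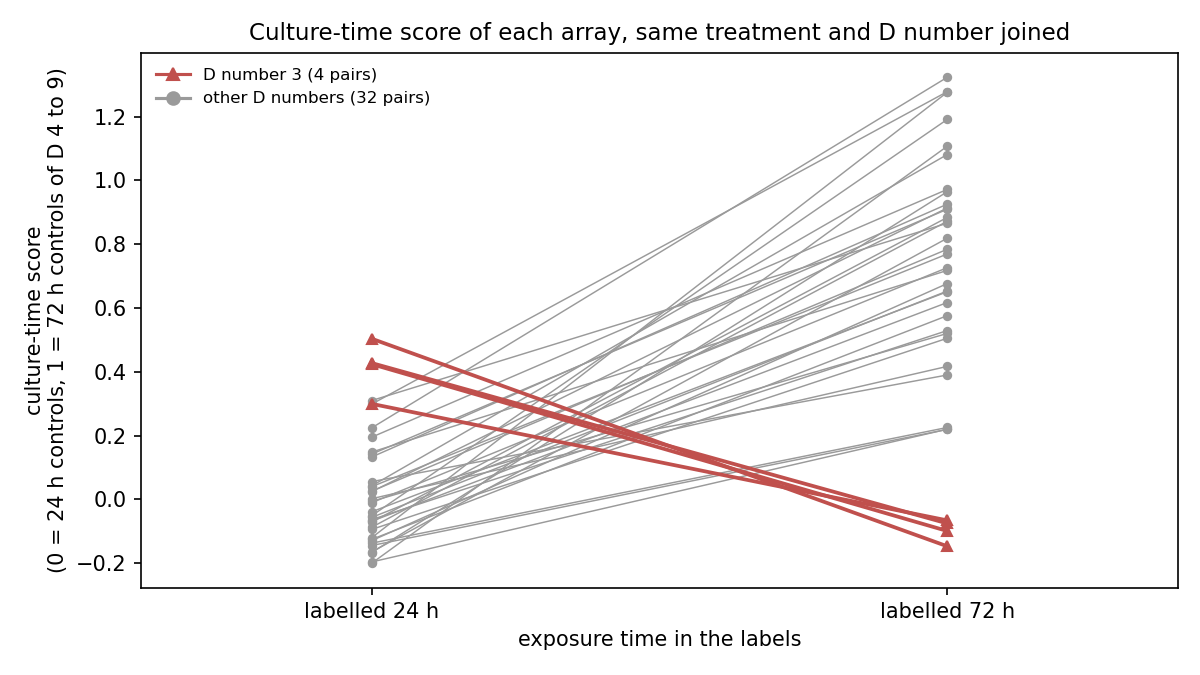
Culture-time score (no unit, 0 and 1 for the means of the 24 h and 72 h controls outside the set of D number 3) of each array, with lines joining labelled 24 h and 72 h arrays of the same treatment and number. The 4 pairs of D number 3 fell, with labelled 24 h scores of 0.300 to 0.504 and labelled 72 h scores of −0.147 to −0.0656, while the grey lines of the other pairs rose.

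**Figure D2:**
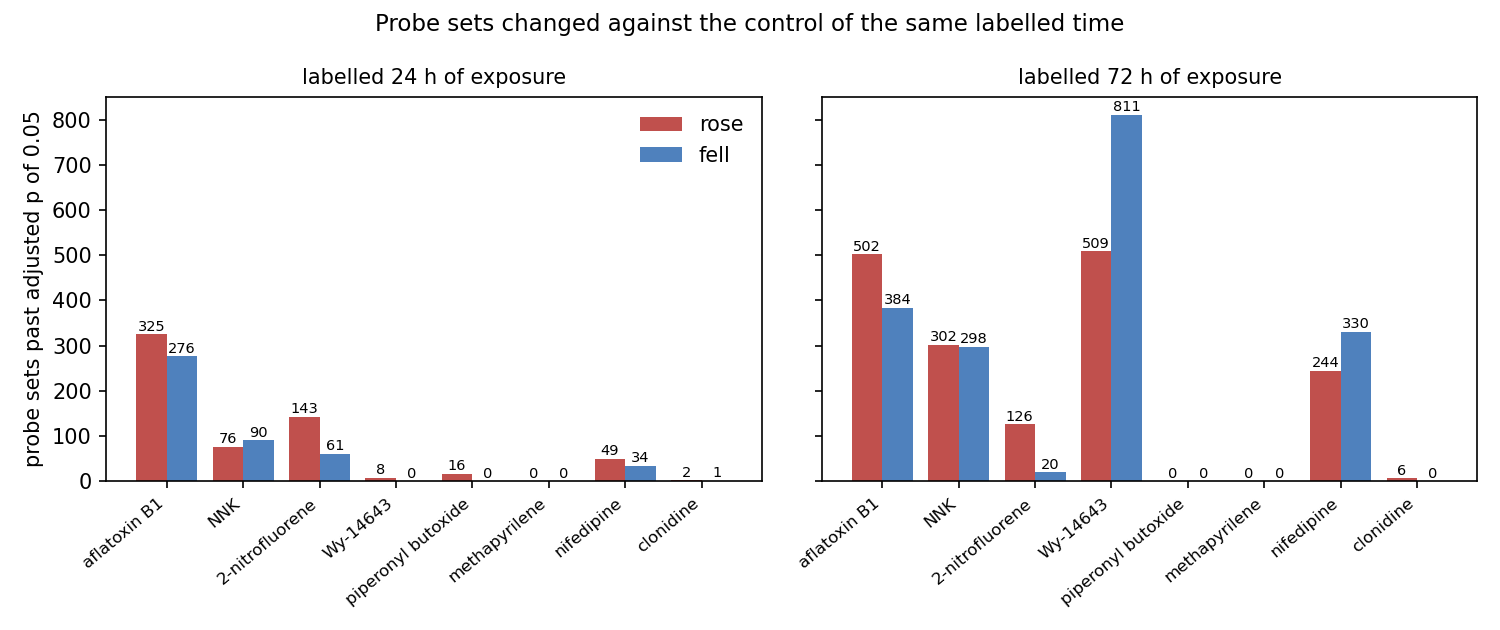
Number of probe sets that rose or fell against the matching control (limma, adjusted p under 0.05) for each compound at 24 h and 72 h, n = 3 arrays per group. The highest count was 1320 after Wy-14643 at 72 h, and methapyrilene gave 0 at both times.

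After 24 h of aflatoxin B1, which the liver turns into a DNA-binding epoxide, the largest rises were in genes of low signal in the control cells. Pln, the regulator of the cardiac calcium pump, rose by 5.92 ± 0.78 on the log2 scale (SE, 3 arrays per group, adjusted p = 4.62e-07), the metalloprotease gene Adam8 by 5.33 ± 0.69, Spetex2l2 by 4.60 ± 0.52 and Cib2 by 4.33 ± 0.56. Fhit, a tumour suppressor gene that spans a fragile site, fell by 3.95 ± 0.47, Lrmda by 3.93 ± 0.65 and Cmss1 by 3.22 ± 0.40. Of the 3 treated arrays 1 was at the floor for Fhit and 2 for Lrmda. Psat1 and Phgdh, which encode enzymes of serine synthesis, fell by 3.22 ± 0.36 and 2.90 ± 0.28. Among 27 measured genes of the p53 and DNA damage list, 14 rose and 0 fell (17 rose adjusted over the list alone), and camera called the list (adjusted p = 0.000125). They included Gdf15 (2.73 ± 0.46), the p53 ubiquitin ligase gene Mdm2 (1.96 ± 0.30), Phlda3 (1.73 ± 0.23), Pidd1 (1.65 ± 0.28), the p21 gene Cdkn1a (1.45 ± 0.21) and the cyclin G1 gene Ccng1 (1.40 ± 0.24). Of 31 ER stress and ATF4 targets, 7 fell and 0 rose (7 and 1 adjusted over the list alone), but the list was not called (adjusted p = 0.623). In all 601 probe sets passed, 325 up and 276 down. Markers of macrophages were not called, but their mean change was 0.758, with 15 of 16 higher (adjusted p = 0.861). The count was 1121 with the replicate block, although the numbers did not pair for this compound, 971 with the actin ratio as a covariate and 307 without aflatoxin B1 replicate 3, whose culture-time score ran against its label. Without the 10 arrays of high actin ratio it was 330 and Gdf15 was not called (2.13, adjusted p = 0.125), but that fit holds 1 aflatoxin B1 array, assumed to vary like the other groups, against 2 controls, so it does not separate RNA quality from sample number.

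After 72 h of aflatoxin B1 the same direction was seen for Pln (6.15 ± 0.78, adjusted p = 1.15e-07), Spetex2l2 (5.51 ± 0.52), Cib2 (4.89 ± 0.56), Fhit (−3.93 ± 0.47), Psat1 (−2.69 ± 0.36) and Phgdh (−2.33 ± 0.28). Pinlyp rose by 4.86 ± 0.59 from controls of which 2 of 3 arrays were at the floor, and Sugct (−3.40 ± 0.41), Macrod1 (−3.35 ± 0.50) and Pik3c2g (−3.34 ± 0.48) fell. For each of the latter genes 1 of 3 treated arrays was at the floor. Of the p53 list 15 of 27 rose and 0 fell (17 rose and 1 fell adjusted over the list alone; adjusted p = 0.000903), with Gdf15 at 2.67 ± 0.46, Mdm2 at 2.18 ± 0.30, Phlda3 at 2.00 ± 0.23, the nuclease gene Aen at 1.68 ± 0.25, Ccng1 at 1.59 ± 0.24 and Cdkn1a at 1.36 ± 0.21. ER stress and ATF4 targets gave 1 rise and 6 falls (1 and 9 adjusted over the list alone; adjusted p = 0.554). Of the 886 probe sets that passed, 502 rose and 384 fell, and of those called at 24 h, 232 rose and 151 fell at both times (9.04 and 5.87 by chance from independent lists). The arrays were different ones but of the same D numbers, and the time labels of D number 3 are unsettled. Markers of macrophages were not called, but their mean change was 1.13, with 16 of 16 higher (adjusted p = 0.698). The count was 1534 with the replicate block, where again the numbers did not pair, 2349 without the D number 3 arrays, whose culture-time scores ran against their labels, and 409 without the 10 arrays of high actin ratio, a fit with 1 aflatoxin B1 array, assumed to vary like the other groups, against 2 controls. It was also 1609 without aflatoxin B1 replicate 1, 276 without replicate 2 and 423 without control replicate 2.

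NNK had its own control, and its genes at 24 h overlapped those of aflatoxin B1. Pln rose by 4.27 ± 0.78 (SE, 3 arrays per group, adjusted p = 0.00096), Adam8 by 4.18 ± 0.69, the matrix link protein gene Hapln3 by 3.14 ± 0.58 and Spetex2l2 by 2.97 ± 0.52, and Fhit fell by 3.04 ± 0.47 (1 of 3 NNK arrays at the floor). Of the p53 list 9 of 27 rose and 0 fell (12 adjusted over the list alone; adjusted p = 0.00125), with Mdm2 at 1.61 ± 0.30, Ccng1 at 1.27 ± 0.24, Phlda3 at 1.26 ± 0.23 and Cdkn1a at 1.01 ± 0.21. There were 52 probe sets that rose after both NNK and aflatoxin B1 at 24 h (1.37 by chance from lists of these sizes) and 40 that fell after both (1.38 by chance). Of 166 probe sets that passed after NNK, 76 rose and 90 fell. With the replicate number as a block 377 passed, 492 without the 10 arrays of high actin ratio (none of them NNK arrays), 264 with the actin covariate and 344 without D number 3. The count was 75, 67 and 86 without control replicates 1, 2 and 3, and 367, 45 and 36 without NNK replicates 1, 2 and 3, where Cdkn1a lost its call without replicate 2 (adjusted p = 0.0631) and 3 (0.127).

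At 72 h of NNK Hapln3 rose by 4.43 ± 0.58 (adjusted p = 1.78e-06), Adam8 by 3.92 ± 0.69, Spetex2l2 by 3.86 ± 0.52 and Pln by 3.77 ± 0.78, while Fhit (−3.13 ± 0.47), Sugct (−2.47 ± 0.41) and Pik3c2g (−2.47 ± 0.48) fell. For Fhit 1 NNK array was at the floor. Of the p53 list 10 of 27 rose and 0 fell (15 rose and 1 fell adjusted over the list alone; adjusted p = 0.00196), with Gdf15 at 2.69 ± 0.46, Mdm2 at 2.03 ± 0.30, Cdkn1a at 1.81 ± 0.21, Phlda3 at 1.41 ± 0.23 and Ccng1 at 1.24 ± 0.24. Of 21 genes of fatty acid synthesis 5 fell (9 adjusted over the list alone), among them the desaturase gene Scd (−1.66 ± 0.32) and the acetyl-CoA synthetase gene Acss2 (−1.41 ± 0.30), as did 5 of 19 genes of cholesterol synthesis (8 adjusted over the list alone). Neither list was called (adjusted p = 0.228 and 0.197). In all, 302 probe sets rose and 298 fell (600), of which 170 rose and 104 fell after aflatoxin B1 too (8.4 and 6.34 by chance). The count was 1296 with the replicate block, 1922 without the high actin arrays, 1293 with the actin covariate and 1336 without D number 3. It was 220 without control replicate 3, 243 without NNK replicate 1 (Scd −1.17, adjusted p = 0.0534) and 242 without NNK replicate 2 (Acss2 −1.18, adjusted p = 0.0541).

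2-Nitrofluorene gave another profile at 24 h, with rises in genes of fatty acid use. Acot1, an acyl-CoA thioesterase, rose by 8.85 ± 1.28 (SE, 3 arrays per group, adjusted p = 1.11e-05) from controls of which 2 of 3 arrays were at the floor, the ω-hydroxylase gene Cyp4a1 by 5.58 ± 0.94, Nim1k by 4.81 ± 0.70, the pyruvate dehydrogenase kinase gene Pdk4 by 4.59 ± 0.87, the peroxisomal enzyme gene Ehhadh by 4.42 ± 0.66 and the carnitine palmitoyltransferase gene Cpt1b by 2.90 ± 0.57. Of 41 PPARα targets 29 rose and 0 fell (34 adjusted over the list alone; adjusted p = 0.00104). Markers of macrophages had a mean change of −0.63, with 1 of 16 higher (adjusted p = 0.964). Of 26 targets of NRF2, the regulator of the oxidative stress response, 6 rose and 0 fell (17 adjusted over the list alone; adjusted p = 0.000903), and the aflatoxin aldehyde reductase gene Akr7a3 rose by 1.98 ± 0.34. The transporter genes Abca8a (−2.17 ± 0.29) and Slc2a2 (−1.44 ± 0.26) fell. The p53 targets Mdm2 (0.34 ± 0.30, adjusted p = 0.811) and Cdkn1a (−0.11 ± 0.21, 0.951) did not pass, nor did the AhR target Cyp1a1 (2.63 ± 0.81, 0.103). There were 143 rises and 61 falls, 204 in all. The count was 591 with the replicate block, 791 without the high actin arrays, 491 with the actin covariate and 564 without D number 3. It was 110 and 94 without control replicates 1 and 3, and 108 and 113 without 2-nitrofluorene replicates 2 and 3.

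After 72 h of 2-nitrofluorene Acot1 (9.17 ± 1.28, adjusted p = 8.75e-06), Ehhadh (4.65 ± 0.66), Cpt1b (3.69 ± 0.57) and the fatty acid binding protein gene Fabp1 (3.78 ± 0.68) were higher, with 2 of 3 control arrays of Acot1 at the floor. Cyp1a1 rose by 3.87 ± 0.81 and Akr7a3 by 1.66 ± 0.34. Of the PPARα list 28 of 41 rose and 0 fell (35 adjusted over the list alone; adjusted p = 0.000903), and of NRF2 targets 3 rose (6 adjusted over the list alone), a list that was not called (adjusted p = 0.0932). The macrophage markers had a mean change of −1.10, with 0 of 16 higher, and 0 called by limma (camera adjusted p = 0.597). Mdm2 (0.21 ± 0.30, adjusted p = 0.954) and Cdkn1a (0.19 ± 0.21, 0.924) did not pass. Of 146 probe sets 126 rose and 20 fell. Of these, 68 had risen and 3 had fallen at 24 h (0.998 and 0.0676 by chance), and 70 rose and 9 fell after Wy-14643 at 72 h too, which had another control group (3.55 and 0.899 by chance). The count was 305 with the replicate block, 420 without the high actin arrays, 232 with the actin covariate and 318 without D number 3. It was 90, 52 and 89 without control replicates 1, 2 and 3, and 60 and 39 without 2-nitrofluorene replicates 1 and 3.

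Wy-14643 raised 8 probe sets at the labelled 24 h, among them 4 of the PPARα and fatty acid oxidation list: Ech1 (1.99 ± 0.39, SE, 3 arrays per group, adjusted p = 0.0181), the carnitine carrier gene Slc25a20 (1.54 ± 0.30), Eci1 (1.52 ± 0.26) and Decr1 (1.43 ± 0.28). Acat1, outside that list, rose by 1.56 ± 0.31, while its other probe set did not pass. Markers of macrophages had a mean change of −0.889, with 0 of 16 higher (2 fell adjusted over the list alone; adjusted p = 0.684). Cyp4a1 (2.54 ± 0.94, adjusted p = 0.291), Ehhadh (2.49 ± 0.66, 0.108) and Cpt1b (2.45 ± 0.57, 0.0692) did not pass. For Ech1 the changes in the 3 pairs of equal number were 1.25, 0.982 and 3.73. Of 41 PPARα targets 4 rose over all probe sets and 35 adjusted over the list alone, and camera called the list (adjusted p = 0.0282). That call was lost with a list mean as large as the 1.41 reported with the replicate block (adjusted p = 0.0699, mean 1.41), with the actin covariate (0.068, 1.42) and without replicate 1 (0.205, 1.79). It was lost with a smaller mean of 0.587 without the high actin arrays (0.108), without D number 3 (0.109) and without replicate 3 (0.067), which leave out the same arrays of Wy-14643 and its control. The replicate 3 arrays are those whose culture-time scores ran against their labels by −0.510. Without D number 3 0 probe sets passed. Without Wy-14643 replicate 3 alone 1 passed and each of the 5 genes lost its call (adjusted p = 0.576), and without control replicate 3 alone 1 passed and Ech1 (0.402), Acat1 and Slc25a20 (0.754) and Decr1 (0.544) lost theirs. The count was 101 with the block, 17 with no filter, 1 without the high actin arrays, 50 with the covariate, 111 and 217 without control replicates 1 and 2, and 89 and 79 without Wy-14643 replicates 1 and 2.

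At the labelled 72 h Wy-14643 changed 1320 probe sets, 509 up and 811 down. Acot1 was higher by at least 9.90 (SE 1.28, adjusted p = 7.82e-07), as all 3 control arrays were at the floor, Pdk4 by 5.95 ± 0.87, Cpt1b by 4.82 ± 0.57, the cytochrome P450 gene Cyp2e1 by 4.24 ± 0.85, the protease inhibitor gene Serpine2 by 4.14 ± 0.72 and Ehhadh by 2.89 ± 0.66. The uptake carrier genes Slco1a4 (−4.12 ± 0.71) and Slco1a1 (−3.04 ± 0.59), the pyruvate kinase gene Pklr (−4.10 ± 0.59), Gstm3 (−2.85 ± 0.47), the urea cycle gene Otc (−2.65 ± 0.52) and the plasma protein gene Ahsg (−1.70 ± 0.25) fell. Each fell in all 3 pairs, but the shared spread behind these SEs can be too small for this set. The pair changes were −0.481, −3.55 and −3.92 for Otc and −1.66, −5.36 and −5.34 for Slco1a4, and the treated Gstm3 arrays had an SD of 1.37. Of the PPARα list 31 of 41 rose and 0 fell (38 adjusted over the list alone; adjusted p = 0.0468), with a mean of 2.16. The call was lost with the replicate block (0.117), without the eBayes trend (0.0508), with the actin covariate (0.0956) and without replicate 1 (0.497), but the list means were 2.16, 2.16, 2.16 and 1.94. Of 33 genes of hepatocyte function 12 fell and 1 rose, of 18 genes of bile acid synthesis and transport 5 fell, of 24 acute phase genes 5 fell, and of 31 genes of the cytoskeleton 6 fell (18, 8, 7 and 12 calls adjusted over the list alone). Markers of macrophages moved with them, as 5 of 16 fell (10 adjusted over the list alone). None of these 5 lists was called (adjusted p = 0.535, 0.587, 0.68, 0.636 and 0.554). The count was 2377 with the block, 2268 without the high actin arrays, 708 without control replicate 2, and 2731 and 421 without Wy-14643 replicates 1 and 2. The D number 3 arrays, whose culture-time scores ran against their labels, were part of both groups, and 1666 passed without them.

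Piperonyl butoxide raised 16 probe sets and lowered 0 at 24 h. The highest were Cyp4a1 (4.94 ± 0.94, SE, 3 arrays per group, adjusted p = 0.00664), Aig1 (2.79 ± 0.49), Ech1 (2.32 ± 0.39) and Eci1 (2.07 ± 0.26). Of 41 PPARα targets 9 rose and 0 fell (31 adjusted over the list alone; adjusted p = 0.00118). Cyp4a1 lost its call without control replicate 1 (adjusted p = 0.0534) or 3 (0.0771) and without piperonyl butoxide replicate 2 (0.0839), as did Aig1 without the latter (0.075). The count was 31 with the replicate block, 83 without the high actin arrays, 26 with the actin covariate, 64 without D number 3, 4, 10 and 7 without control replicates 1, 2 and 3, and 4 without piperonyl butoxide replicate 2. At 72 h limma called 0 probe sets, with 196 of 18048 at an unadjusted p under 0.05. That lies below a share of 0.05, but so did the 685 at 24 h, so it does not show an absence of a response. The changes there of Cyp1a1 (3.13 ± 0.81), Cyp1a2 (2.54 ± 1.02) and Cyp4a1 (1.48 ± 0.94) had adjusted p = 1, and 1 probe set passed with the block and 1 without control replicate 3. These SEs use the shared spread. For Cyp1a1 the SDs were 0.495 over the treated arrays and 0.263 over their controls, with changes of 3.89, 3.12 and 2.37 in the 3 pairs. Of 41 PPARα targets 34 were higher at 72 h (mean 0.451), but camera did not call the list (adjusted p = 0.504).

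Methapyrilene at 8.5 µM gave 0 calls by limma at 24 h and at 72 h, with 413 and 322 probe sets at an unadjusted p under 0.05. Both lie below a share of 0.05 of the 18048 tested, as did the 685 after piperonyl butoxide at 24 h, where 16 probe sets passed. The fit does not use the pairing of arrays and pools its spread over all groups. A count below that share therefore does not tell whether a response remained, nor do the 0 calls show an absence of one. Mdm2 differed from its control by 0.54 ± 0.30 (SE, 3 arrays per group) at 24 h and 0.23 ± 0.30 at 72 h, and the heme oxygenase gene Hmox1 by −0.50 ± 0.54 and 0.79 ± 0.54. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by −0.60 ± 0.93 and −1.70 ± 0.93. Each of these 6 changes had adjusted p = 1. With no filter on dim probe sets 27 and 5 passed, and 2 passed without control replicate 2 at 24 h and 2 without methapyrilene replicate 3 at 72 h.

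Nifedipine changed 83 probe sets at 24 h, 49 up and 34 down. Cyp1a1 rose by 3.45 ± 0.81 (SE, 3 arrays per group, adjusted p = 0.028), the stress gene Ddit4l by 3.15 ± 0.56, Hmox1 by 2.74 ± 0.54, the transcription factor gene Maff by 2.18 ± 0.40 and the efflux pump gene Abcc2 by 1.23 ± 0.23, and Rab11fip4 fell by 1.51 ± 0.23. Of 26 NRF2 targets 7 rose and 0 fell (14 adjusted over the list alone; adjusted p = 8.13e-05). Markers of macrophages had a mean change of −0.393, with 0 of 16 higher and 0 called by limma (camera adjusted p = 0.964). Cyp1a1 lost its call with no floor (adjusted p = 0.0792) and without control replicate 1 (0.16) or 3 (0.159) or nifedipine replicate 1 (0.135) or 2 (0.171), Hmox1 without control replicate 1 (0.0516) or 3 (0.0587) or nifedipine replicate 2 (0.152), and Ddit4l without control replicate 1 (0.0572). The count was 332 with the replicate block, 388 without the high actin arrays, 175 with the actin covariate, 225 without D number 3, 9 and 37 without control replicates 1 and 3, and 51, 11 and 150 without nifedipine replicates 1, 2 and 3.

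After 72 h nifedipine changed 574 probe sets, 244 up and 330 down. Cyp1a1 rose by 5.03 ± 0.81 (adjusted p = 9.65e-05), the defensin gene Defb1 by 3.91 ± 0.59, Ddit4l by 3.20 ± 0.56 and Abcc2 by 2.09 ± 0.23. The NRF2 list had 15 of 26 members higher and 0 lower (19 adjusted over the list alone; adjusted p = 6.46e-06), among them Hmox1 (3.58 ± 0.54), the glutathione transferase gene Gstp1 (3.45 ± 0.52), the quinone reductase gene Nqo1 (2.89 ± 0.52) and the sulfiredoxin gene Srxn1 (2.85 ± 0.41). The cytochrome P450 gene Cyp2c13 (−3.40 ± 0.62), S1pr1 (−3.12 ± 0.45), Akr1c1 (−3.06 ± 0.59) and Rprm (−2.98 ± 0.65) fell, the last pair to the floor on 2 of 3 arrays. Markers of macrophages moved too, as 4 of 16 fell (10 adjusted over the list alone; adjusted p = 0.535), among them Aif1 (−2.59 ± 0.59, 2 of 3 nifedipine arrays at the floor). Of 10 AhR targets 2 rose (2 adjusted over the list alone), of 18 CAR and PXR targets 3 rose (7), of 11 foetal liver markers 2 rose (4), and of 32 cell cycle genes 3 fell (14). Of 21 fatty acid synthesis genes 5 fell and 1 rose (10 falls adjusted over the list alone). None of these lists was called (adjusted p = 0.382, 0.196, 0.548, 0.436 and 0.384), and the foetal liver list had a median of −0.26 beside a mean of 0.53. Of the probe sets called at 24 h, 31 rose and 11 fell at both times (0.662 and 0.622 by chance) and 1 went opposite ways. The count was 1405 with the replicate block, 1731 without the high actin arrays, 1092 with the actin covariate, 1344 without D number 3, 263, 159 and 356 without control replicates 1, 2 and 3, and 148 and 334 without nifedipine replicates 1 and 3. Aif1 lost its call without control replicate 2 (adjusted p = 0.0945) and nifedipine replicate 1 (0.0701). Of the calls 42.5% were rises, and 54.5% of 479 after quantile normalization.

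Clonidine changed 3 probe sets at the labelled 24 h and 6 at 72 h. At 24 h these were a probe set of Aebp2, which fell by 1.05 while the other probe sets of that gene did not pass and which was chosen after its values were seen and lost its call without D number 3 (−0.76, adjusted p = 0.922), 1 without a gene name, and Htatip2. The latter rose by 1.04 ± 0.17 (SE, 3 arrays per group, adjusted p = 0.00121), a call lost without D number 3 (0.90, adjusted p = 0.068), and Hmox1 did not pass (2.06 ± 0.54, adjusted p = 0.267). At 72 h Hmox1 (3.10 ± 0.54, adjusted p = 0.00232), the lysosomal glycoprotein gene Gpnmb (2.36 ± 0.39) and Maff (2.31 ± 0.40) rose. Of 26 NRF2 targets 0 rose at 24 h over all probe sets (10 adjusted over the list alone) and 1 at 72 h (11 adjusted over the list alone), and camera called the list at both times (adjusted p = 0.00118 and 0.00104), at 24 h not without replicate 1 (0.171, mean 0.518 in place of 0.662). Hmox1 lost its call without control replicate 1 (adjusted p = 0.141) or clonidine replicate 3 (0.0589), and Maff likewise (0.0778 and 0.0808). Of the 3 calls at 24 h 66.7% were rises, and 100% of 3 after quantile normalization. The count at 24 h was 11 with the replicate block, 7 with no filter, 6 without the eBayes trend, 5 without the high actin arrays, 8 with the covariate, 19 and 89 without control replicates 1 and 2, and 1 without clonidine replicate 1. At 72 h it was 16, 14 and 13 with the block, with no filter and without the high actin arrays, 1 without control replicate 1 and 2 without clonidine replicate 3. The replicate 3 arrays, whose culture-time scores ran against their labels, were in both groups.

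**Figure D3:**
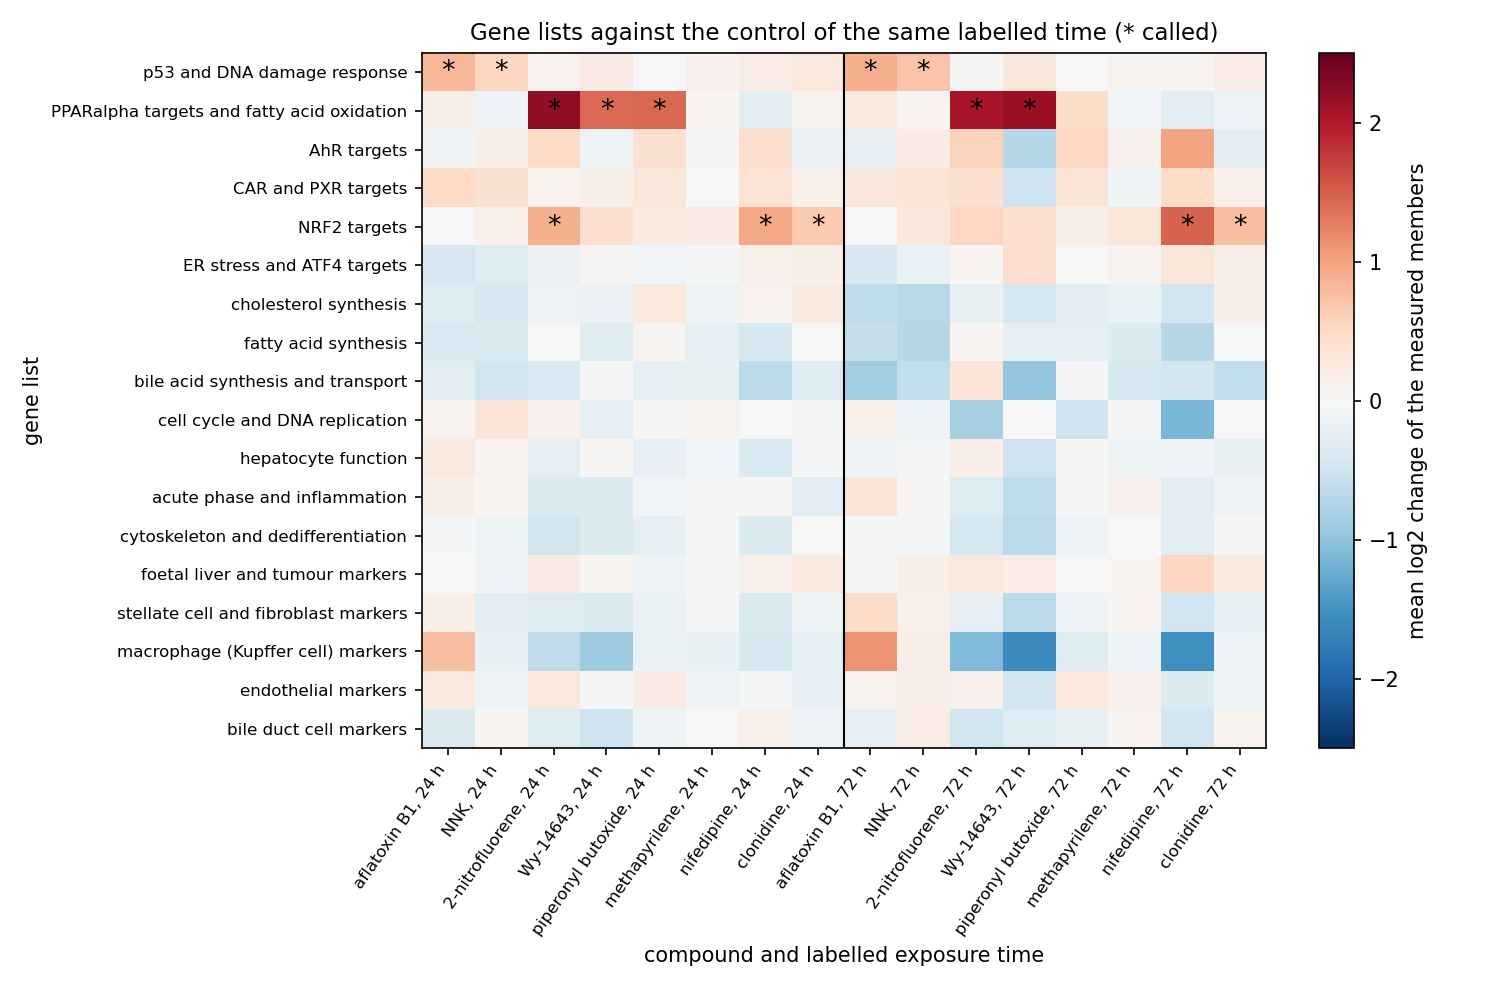
Mean log2 change (colour) of the measured members of each of the 18 gene lists, by compound and labelled time, with a star where camera called the list at an estimated correlation. The 14 stars lie in the PPARα, p53 and NRF2 lists.

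Over the 18 lists and 16 comparisons camera with an estimated correlation called 14 of 288 tests, each with a positive mean change: 5 for PPARα targets, 4 for the p53 list and 5 for NRF2 targets. A preset correlation of 0.01 called 88, which include these 14. Markers of endothelial cells (9 measured), stellate cells and fibroblasts (13) and bile duct cells (6) gave 0 calls by limma in all 16 comparisons. Of their member tests 1 of 144, 5 of 208 and 7 of 96 had an unadjusted p under 0.05, and 0, 1 and 4 passed adjusted over the list alone. The controls are shared within each set, so these comparisons are not independent of one another.

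**Figure D4:**
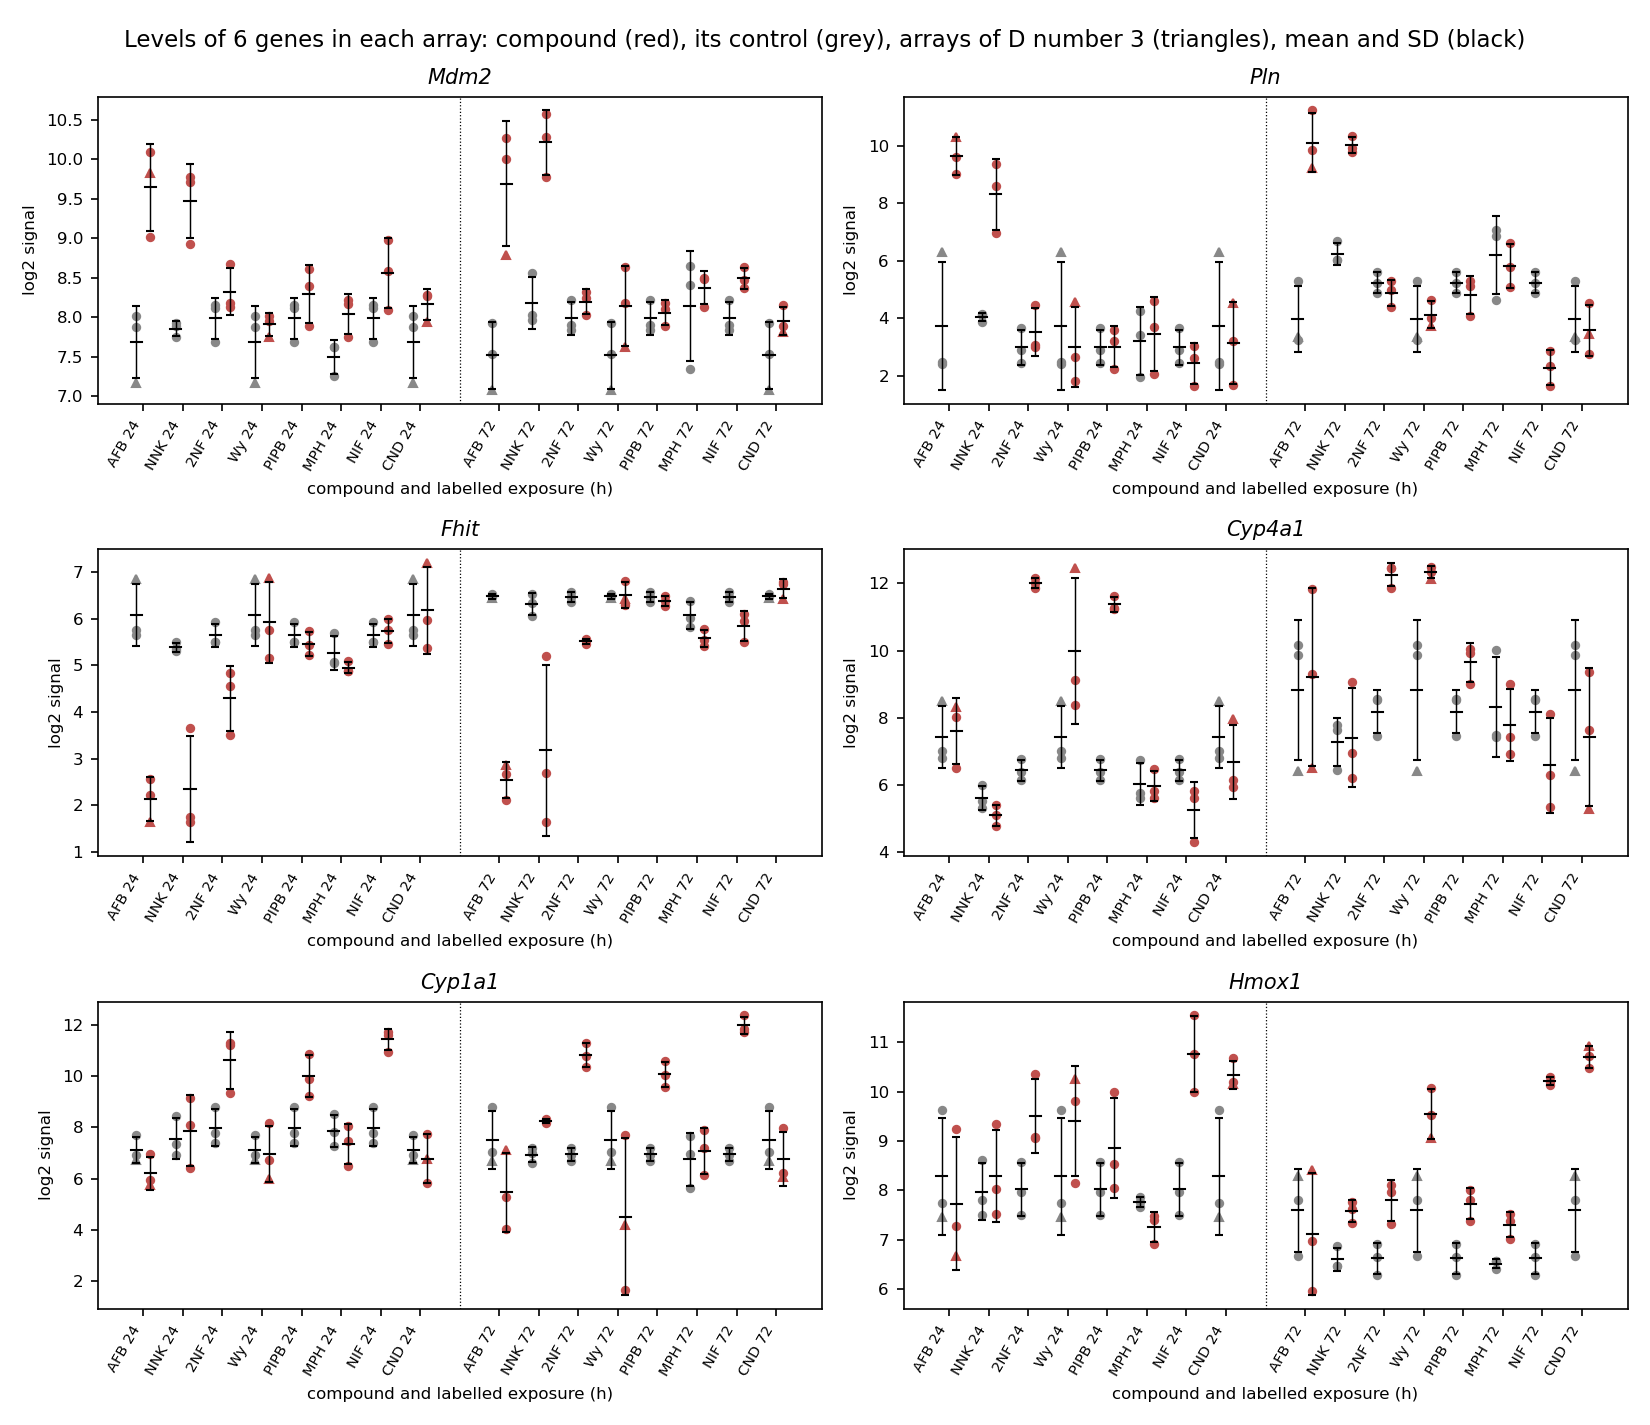
Log2 signal of 6 genes on each array by compound (red), control (grey) and labelled time, with triangles for D number 3 and black bars for the mean and SD of 3 arrays. Mdm2 lies higher after aflatoxin B1 (9.64 at 24 h) and NNK (9.47) than in their controls (7.68 and 7.86).

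The mean change over the p53 list was 0.486 ± 0.373 at 24 h over the 3 genotoxic compounds and 0.149 ± 0.105 over the other 5 (SD), a difference of 0.337 (two-sided exact permutation p = 0.107). At 72 h it was 0.542 ± 0.457 against 0.119 ± 0.113, a difference of 0.423 (exact permutation p = 0.0893). The 56 splits allow a p of 0.0179 at the least. The compounds of the genotoxic class lay apart, with 0.836 and 0.882 for aflatoxin B1 at 24 h and 72 h, 0.529 and 0.722 for NNK and 0.093 and 0.022 for 2-nitrofluorene.

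As mean effects of classes, the genotoxic carcinogens differed from the non-genotoxic ones at 24 h by higher Pln (3.73 ± 0.52, SE), Spetex2l2 (2.65 ± 0.35) and Gbp4 (2.32 ± 0.30) and lower Fhit (−2.56 ± 0.31), Cmss1 (−1.82 ± 0.27) and Phgdh (−1.46 ± 0.19) (180 probe sets, 102 up and 78 down). At 72 h among the largest differences were Pln (3.40 ± 0.52), Adam8 (3.22 ± 0.46), Spetex2l2 (2.95 ± 0.35) and Hapln3 (2.93 ± 0.39), with Fhit (−2.49 ± 0.31) and Serpinb9b (−1.79 ± 0.30) lower (400 probe sets, 256 up and 144 down). The carcinogens differed from the non-carcinogens at 24 h by 149 probe sets (87 up, 62 down), with Cyp4a1 higher by 3.08 ± 0.58 and Psat1 (−1.39 ± 0.23), Hmox1 (−1.95 ± 0.34) and Maff (−1.67 ± 0.25) lower. At 72 h 609 probe sets differed (334 up, 275 down), with Pln (3.15 ± 0.48) and the gluconeogenic gene Pck1 (2.80 ± 0.36) higher and Defb1 (−2.57 ± 0.37), Hmox1 (−2.42 ± 0.34), Maff (−1.78 ± 0.25) and Srxn1 (−1.69 ± 0.26) lower. A class mean is carried by its strongest compounds, and the spread here is that of arrays within groups, not of compounds within a class. Lower is also relative to the non-carcinogens and need not be a fall. Hmox1 at 72 h rose by 3.58 after nifedipine, 3.10 after clonidine and 1.96 after Wy-14643, with −0.48 after aflatoxin B1 not called. Defb1 rose by 3.91 after nifedipine at 72 h. In that order the 4 counts were 314, 812, 382 and 1244 with the replicate block. Without the high actin arrays they were 356, 727, 265 and 1014. The 24 h counts were 239 and 225 with the actin covariate and 317 and 199 without D number 3, where the 72 h ones were 1048 and 1043, and the 72 h carcinogen count with the covariate was 923. Without replicate 1, 2 or 3 of every group they were 103, 26 and 71, then 134, 49 and 358, then 7, 25 and 84, then 74, 118 and 530. Cyp4a1, Hmox1 and Maff at 24 h lost their calls without replicate 1.

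The change from 24 h to 72 h of exposure was tested as a difference of effects. For nifedipine it passed at 21 probe sets, 19 of them higher at 72 h, among them Epn1 (3.23 ± 0.65, SE), Ubl5 (1.97 ± 0.29) and Adrm1 (1.88 ± 0.33), with Ccar1 lower (−1.13 ± 0.20). For NNK it passed at 5, with Cln3 (2.73 ± 0.53), both probe sets of Ubl5 (1.66 ± 0.29 and 1.82 ± 0.34) and S100a14 (3.58 ± 0.74, chosen after its values were seen and not called with no floor, adjusted p = 0.395) higher and Ccar1 (−0.99 ± 0.20) lower. For 2-nitrofluorene it passed at 1, Abca8a (2.47 ± 0.41). The other probe sets of Cln3 and Ccar1 did not pass. For the other 5 compounds limma called 0, with 1156 (Wy-14643), 191 (clonidine), 438 (aflatoxin B1), 236 (piperonyl butoxide) and 184 (methapyrilene) at an unadjusted p under 0.05. Of these only the count of Wy-14643 lies above a share of 0.05 of the 18048 tested. The counts of NNK (874) and 2-nitrofluorene (700), which had calls, lie below it too, so a lower count does not show an absence of a difference. Without replicate 1, 2 or 3 of every group, and so with fewer samples, nifedipine gave 0, 0 and 33, NNK 3, 0 and 0, 2-nitrofluorene 0 each time and Wy-14643 10, 0 and 58. Each gene named for these differences lost its call in at least 2 of those 3 fits. With the replicate block the counts were 59 for nifedipine, 14 for NNK, 4 for 2-nitrofluorene and 11 for Wy-14643, and without the high actin arrays 88, 64, 9 and 210, with 3 for piperonyl butoxide and 8 for aflatoxin B1, which then had 1 array at each time. Without D number 3 they were 49, 23, 5 and 121, with the actin covariate 45 for nifedipine, 47 for NNK and 5 for Wy-14643, and with no filter 8 for NNK, 3 for 2-nitrofluorene and 8 for methapyrilene. The time labels of D number 3, which enters the contrasts of Wy-14643, clonidine and aflatoxin B1, are unsettled. Exchanged labels would turn the sign of its difference, so the 0 calls of these compounds do not show the same effect at both times.

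Between the 24 h and 72 h exposure times the control cells themselves changed at 2872 probe sets, 1752 up and 1120 down. These times count from the start of exposure, which came some hours after plating, so the cells had been in culture for longer. Cd24, a marker of progenitor and bile duct cells (4.40 ± 0.66, SE), Dtna (3.08 ± 0.41) and Slc24a3 (2.81 ± 0.33) were higher at 72 h, and Fabp4 (−3.96 ± 0.61), Serpina3l (−3.48 ± 0.53), the steroid carrier gene Serpina6 (−3.09 ± 0.53), Cyp1a2 (−3.03 ± 0.51) and Cyp2e1 (−2.84 ± 0.42) lower. The control arrays of D number 3 entered this contrast with their labels as given. The count was 5297 without the high actin arrays, 4647 without D number 3, and 1246, 315 and 3000 without replicate 1, 2 or 3 of every group. The controls of NNK and of the 2-nitrofluorene set, which share their D numbers, differed at 0 probe sets by limma at both times, with 411 and 419 at an unadjusted p under 0.05. Both lie below a share of 0.05 of the 18048 tested, but the test does not use the pairing by D number, so this does not show an absence of a difference. With no filter 3 and 6 passed, and 1 at each time without NNK control replicate 1.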

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

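The exchange of labels with Wy-14643 arrays and the 3 tests on aflatoxin B1 were chosen after the results were seen, as was the fit without the D number 3 arrays. The effect against the control differed between 24 h and 72 h of exposure at 21 probe sets for nifedipine, 5 for NNK and 1 for 2-nitrofluorene, by limma's test of the difference itself. For nifedipine these hold Epn1 (3.23), Ubl5 (1.97), Adrm1 (1.88) and Ccar1 (−1.13), for NNK Cln3 (2.73), Ubl5 (1.66) and Ccar1 (−0.99), and for 2-nitrofluorene Abca8a (2.47). Other draws of the labels within each time gave as many in 7 of 100 for nifedipine (highest other 828), 9 of 100 for NNK (1053) and 13 of 100 for 2-nitrofluorene (606), so that chance is not excluded. The draws that mirror the labels at 1 time add real effects and raise their counts.

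The D number 3 arrays of Wy-14643, clonidine, aflatoxin B1 and their control stood apart. Their culture-time score changed from the labelled 24 h to the labelled 72 h by −0.510 on average, in 4 of 4 pairs, from 0.300 to 0.504 at the labelled 24 h to −0.147 to −0.0656 at 72 h, where 6 pairs of D numbers 1 and 2 of the same set lay at −0.196 to 0.0399 and 0.220 to 0.784. RNA quality alone is argued against by the 2 other pairs that hold a high actin array, where the score rose by 0.651, although 2 pairs are few and degradation could act otherwise in a whole batch. An exchange of the 24 h and 72 h labels of this batch is a candidate explanation, since both sides lie within the range of the other time in these 6 pairs, although 1 NNK array of another set reached 0.310 at 24 h, and the labels cannot settle it. Until it is settled the time of the replicate 3 arrays in this set is open, and the effect of Wy-14643 at 24 h (0 probe sets without them) rests on it.

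Targets of PPARα rose after 2-nitrofluorene, which the design text places among the genotoxic carcinogens, with list means of 2.22 at 24 h and 2.06 at 72 h. Exchanged labels with the Wy-14643 arrays are argued against, since each 2-nitrofluorene array correlated with the control of its own number (0.308 at the least) in its deviations. RNA quality is argued against too, since no array of the set was over the actin threshold and the lower list mean with the actin ratio as a covariate was 2.05. A response of the receptor to this compound or to a contaminant of its stock stays open, and neither was tested.

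The profile of aflatoxin B1 was weighed because 4 of its 6 arrays showed high actin ratios. A fit with the actin ratio as a covariate cannot weigh RNA quality alone. Its slope comes mainly from the Wy-14643, clonidine and aflatoxin B1 set, with actin SDs within groups of 0.70 to 1.18, against 0.04 to 0.21 elsewhere. Most of the high arrays there are of D number 3, whose culture-time scores ran against their labels. In that fit 601 of the 601 probe sets called at 24 h and 781 of the 886 at 72 h kept their call and direction. Without the 10 arrays 232 and 294 kept it, in fits with 1 aflatoxin B1 array, where the lost calls went from a median size of 0.87 to 0.71 at 24 h and 1.01 to 0.73 at 72 h (median SE 0.23 to 0.28 and 0.26 to 0.33) and the p53 list mean from 0.836 to 0.818 and 0.882 to 0.947, so the loss cannot be assigned to RNA quality. A response shared with NNK, another genotoxic compound with its own control and no array over the threshold, may account for part, since 170 probe sets rose after both at 72 h, where 8.4 would by chance. Whether the unsettled time labels of replicate 3 play a part stays open.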

How the results depend on the processing

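The fits without the 10 high actin arrays, with the actin covariate and without the 8 arrays of D number 3 were chosen after seeing the data. Of 169 gene results tested 0 reversed in any alternative, 151 passed and 122 kept their call in each alternative and with each array left out. These are the genes named in the text, narrowed after the data were seen to those that mostly kept their call. The counts are therefore not an independent measure of robustness. Tested apart, the probe sets of Aebp2 and S100a14 and the second one of Ubl5 for NNK kept their direction and lost calls: Aebp2 after quantile normalization (0.117), without the high actin arrays (0.735) or D number 3 (0.922) and in 4 of 6 fits with 1 array left out, S100a14 after quantile normalization (0.0523), with no floor (0.395) and without any replicate, and Ubl5 without replicate 2 or 3. Depth is limited by the signal over background of dim probe sets and by 3 arrays per group. Counts are given below where they differed from the reported ones by over 1.5 times, and the cause was not tested. The fits without the high actin arrays or D number 3 drop no array of 2-nitrofluorene, piperonyl butoxide, nifedipine, NNK or their controls. Their log2 changes then stay the same, and only the shared spread and the probe sets kept can move their counts. Fits that leave out arrays have fewer samples.

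With the replicate block, at 24 h, the counts were 101 for Wy-14643, 11 for clonidine, 1121 for aflatoxin B1, 591 for 2-nitrofluorene, 31 for piperonyl butoxide, 332 for nifedipine and 377 for NNK, and at 72 h 2377, 16, 1534, 305, 1, 1405 and 1296. Time differences gave 11 (Wy-14643), 4 (2-nitrofluorene), 59 (nifedipine) and 14 (NNK), and the class contrasts, genotoxic first, 314 and 382 at 24 h and 812 and 1244 at 72 h. Arrays 1, 2 and 3 of aflatoxin B1 correlated with the control of their number at −0.265, 0.673 and 0.274 at 24 h and 0.632, −0.286 and 0.546 at 72 h, so the rule for pairing was not met. The 2 negative pairs are those where the treated array alone was over the actin threshold. Every probe set called without the block was called with it in the 16 comparisons, and it ended no call but the list calls of PPARα after Wy-14643.

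With no filter the counts were 17 (Wy-14643), 7 (clonidine) and 27 (methapyrilene) at 24 h, 14 (clonidine) and 5 (methapyrilene) at 72 h, 3, 8 and 8 for the time differences of 2-nitrofluorene, NNK and methapyrilene, and 3 and 6 between controls. Without the trend clonidine gave 6 at 24 h. The preset correlation called 88 list tests, 41 up and 47 down. Quantile normalization and no floor moved no count beyond 1.5 times.

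Without the 10 high actin arrays 1 aflatoxin B1 array was left per time, assumed to vary like the other groups. The counts at 24 h were 1 (Wy-14643), 5 (clonidine), 330 (aflatoxin B1), 791 (2-nitrofluorene), 83 (piperonyl butoxide), 388 (nifedipine) and 492 (NNK), and at 72 h 2268 (Wy-14643), 13 (clonidine), 409 (aflatoxin B1), 420 (2-nitrofluorene), 1731 (nifedipine) and 1922 (NNK). Time differences gave 210 (Wy-14643), 8 (aflatoxin B1, 1 array at each time), 9 (2-nitrofluorene), 3 (piperonyl butoxide), 88 (nifedipine) and 64 (NNK), the class contrasts 356, 265, 727 and 1014, and culture time 5297. With the covariate the counts at 24 h were 50 (Wy-14643), 8 (clonidine), 971 (aflatoxin B1), 491, 26, 175 and 264 (2-nitrofluorene, piperonyl butoxide, nifedipine and NNK), at 72 h 232 (2-nitrofluorene), 1092 (nifedipine) and 1293 (NNK), for time differences 5 (Wy-14643), 45 (nifedipine) and 47 (NNK), and for carcinogens 225 and 923. Without D number 3 they were 0 (Wy-14643), 564, 64, 225 and 344 at 24 h, 2349 (aflatoxin B1), 318, 1344 and 1336 at 72 h, 121, 5, 49 and 23 for the time differences of Wy-14643, 2-nitrofluorene, nifedipine and NNK, 317, 1048 and 1043 for the genotoxic contrasts and the 72 h carcinogen contrast, and 4647 for culture time.

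With 1 array left out the ranges at 24 h were 1 to 217 (Wy-14643), 1 to 89 (clonidine), 307 to 668 (aflatoxin B1), 94 to 196 (2-nitrofluorene), 4 to 13 (piperonyl butoxide), 9 to 150 (nifedipine), 36 to 367 (NNK) and 0 to 2 (methapyrilene), and at 72 h 421 to 2731, 1 to 9, 276 to 1609, 39 to 161, 0 to 1, 148 to 425, 220 to 596 and 0 to 2. Without a replicate number the ranges were 0 to 58 (Wy-14643), 0 (2-nitrofluorene), 0 to 33 (nifedipine) and 0 to 3 (NNK) for time differences, 26 to 103 and 7 to 84 for the class contrasts at 24 h, 49 to 358 and 74 to 530 at 72 h, and 315 to 3000 for culture time. Between controls 1 array left out gave 0 to 1 at both times. The list calls ranged from 12 to 14, and the p53 difference from 0.314 to 0.374 at 24 h and 0.370 to 0.471 at 72 h. Over the other settings it ran from 0.310 to 0.346 and from 0.423 to 0.454, and with the median of the members it was 0.485 (exact permutation p = 0.0714) and 0.489 (0.0893).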

Other observations

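Markers of macrophages, cells that remain in small numbers among isolated hepatocytes, had means of either sign. Over 16 markers the mean was 0.758 at 24 h and 1.13 at 72 h after aflatoxin B1 (15 and 16 higher, 0 called by limma). It was −0.889 and −1.59 after Wy-14643 (0 higher at both times, 5 falls called at 72 h), −0.63 and −1.10 after 2-nitrofluorene (1 and 0 higher, 0 called) and −0.393 and −1.54 after nifedipine (0 higher at both times, 4 falls called at 72 h). After the other 4 compounds it lay between −0.297 and 0.162. Camera called the list in 0 of the 16 comparisons (lowest adjusted p = 0.535), and the difference between compounds was not tested.

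After Wy-14643 at the labelled 72 h, 5 of 31 ER stress and ATF4 targets rose and 0 fell (7 rises adjusted over the list alone, mean 0.415, adjusted p = 0.623), where aflatoxin B1 gave 6 falls. Of 10 AhR targets 3 fell and 0 rose (mean −0.721, adjusted p = 0.665), and of 18 CAR and PXR targets 2 rose and 5 fell (adjusted p = 0.964).

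Whether grouping by chance gives as many calls was counted over other splits of the same arrays. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05, so that the real value and the highest other are given with the number of splits that gave as many. At 24 h these were 204 and 1 for 2-nitrofluorene, 16 and 0 for piperonyl butoxide, 83 and 4 for nifedipine and 166 and 2 for NNK, and at 72 h 146 and 1, 0 and 0, 574 and 0, and 600 and 1, each real split being the 1 split of 10 with as many, or 10 of 10 where the real value was 0. Methapyrilene gave 0 and 1 at 24 h and 0 and 42 at 72 h (10 of 10 both), and the controls of NNK and of the 2-nitrofluorene set 0 and 0 at both times (10 of 10).

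In the set of Wy-14643, clonidine and aflatoxin B1 the highest other splits were above the real ones: 8 and 739 for Wy-14643 (5 of 10 as many), 3 and 894 for clonidine (5 of 10) and 601 and 3772 for aflatoxin B1 (2 of 10) at 24 h, and 1320 and 4697 (2 of 10), 6 and 199 (4 of 10) and 886 and 5172 (2 of 10) at 72 h. These splits put both replicate 3 arrays on 1 side, which points to a structure of the samples, and with the replicate block the real counts for Wy-14643 and clonidine were 101 and 11 at 24 h and 2377 and 16 at 72 h. The numbers pair the arrays of Wy-14643 and clonidine, and among the splits that also part all 3 pairs the highest were 0 and 39 for Wy-14643 and 0 and 0 for clonidine at 24 h and 72 h.

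For contrasts over more arrays the control culture time gave 2872, which 1 of 100 draws reached (highest other 2524), and the gene lists gave 14 calls, which 1 of 40 reached (highest other 1). In both the 1 draw is the real one, so that chance is unlikely for these but not excluded. Swapping compounds between classes gave as many calls in 3 of 10 splits for the genotoxic against the non-genotoxic compounds at 24 h (180, highest other 294) and 3 of 10 at 72 h (400 and 734), which are too few for a share under 0.05. For the carcinogens against the non-carcinogens 5 of 28 splits gave as many at 24 h (149 and 539) and 4 of 28 at 72 h (609 and 1164), so that chance is not excluded. Time differences of the other 5 compounds were 0 and reached by 100 of 100 draws, with highest others of 5695 for Wy-14643, 3973 for clonidine, 6888 for aflatoxin B1, 6 for piperonyl butoxide and 133 for methapyrilene.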
